A study of Arabidopsis thaliana with 18 samples.

How the data were processed

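RNA-seq of Arabidopsis thaliana seeds was analysed from the counts the authors deposited, 1 file for each of 18 libraries. Per the labels, polyadenylated RNA of dry seeds and of dormant seeds imbibed for 24 h in the dark at 25 °C was made into stranded paired-end libraries, from plants grown at 21 °C, and reads were mapped to TAIR10 with TopHat2 and Bowtie2, without versions given. Per the file headers, the authors took counts of read pairs per transcript model from properly paired reads on the same reference and reversed strands, treated singletons as unmapped, set no insert limits and removed pairs with several equally good hits. The column of counts of pairs was used as deposited, as raw counts, with 1 transcript model per locus and 33602 models per file. Symbols came from the TAIR10.1 annotation, in which 32835 loci (97.7%) were found and 10654 have a symbol, and no coordinates are given because the labels name TAIR10. The labels do not say how reads over overlapping or antisense genes were assigned, so such genes need caution.

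Libraries were grouped by genotype and state as labelled, 3 per group in 6 groups. The labels do not say what a replicate number marks. Fixed before the data were examined were the groups, comparisons, gene lists, tests, alternatives and the rule for naming genes. Counted pairs per library ran from 12170793 to 21233207. The CPM values are counts scaled by effective library sizes from TMM factors, which were 0.707 to 0.777 in dry libraries, 1.56 to 1.60 in imbibed wild type, 1.25 to 1.26 in imbibed mpk8 and 1.16 to 1.33 in imbibed libraries labelled tcp14. SE were computed as the absolute log2 fold change divided by the square root of the F statistic of the edgeR test. They cover the spread of libraries and counting and not differences between seed lots, and are approximate for genes with few pairs. Bounds on a fold set a group mean against a floor of counts and do not cover the spread of libraries.

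Genes passing filterByExpr over the 6 groups (18061) were fitted with the quasi-likelihood model of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), 1 mean per group over all libraries. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no minimum fold. Comparisons were imbibition in each genotype, each mutant-labelled line against wild type and the lines against each other in each state, and the interactions of genotype and imbibition, 11 in all, plus the overlap of calls of both lines in each state. A group without any pair was set at a floor of 3 pairs over the group to give a bound on the fold. The 23 gene lists, written from general knowledge, cover ABA synthesis, catabolism and signalling, GA synthesis, catabolism and response, dormancy regulators, LEA, storage and oleosin, cell wall loosening, ribosomal protein, heat shock, lipid mobilisation, replication and cell cycle, jasmonate, reactive oxygen species, TCP, MAP kinase, photosynthesis, flavonoid, seed coat, endosperm and defence genes. Of these, the 20 with at least 3 tested members were tested with camera on log2 CPM with a prior count of 2, an inter-gene correlation of 0.01 and, beside it, an estimated correlation, with adjustment over the lists of a comparison. The overlap was set against independent calls and against 20 simulations without a genotype effect that shared the wild-type libraries.

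Genes named are MPK8 and TCP14 in each comparison, the 8 largest increases and 8 largest decreases (4 each for mpk8 against tcp14) among called genes with a symbol, at least 5 CPM in the higher group and no overlap of libraries between groups (not asked for interactions), up to 4 called members of each list with the largest changes, and the 10 shared genes with the largest changes at 24 h. With 3 libraries on each side, chance gives no overlap in 10% of cases. The fit was tested on simulated data, drawn from negative binomial counts with the means of wild-type libraries and the estimated spread, with 50 genes changed per fold and comparison. Changed genes were drawn only from those expressed in both dry and imbibed wild type, so genes near zero were not covered. Shifts of as many genes as the real comparisons called were not covered either by these simulations. There 1.5-fold changes were found for 84% of genes in dry mpk8, 62% in dry tcp14, 74% in imbibed mpk8 and 82% in imbibed tcp14 comparisons, 2-fold changes for 90% to 98%, and 2.08% to 8.57% of calls were of unchanged genes.

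Alternatives were DESeq2 size factors in edgeR, library totals, the Wald test of DESeq2 1.42.0, all genes with a count, a 2-fold minimum, fits of the compared groups alone, a replicate block and each library left out. Single reads instead of pairs, and leaving out 2 segments of chromosomes 1 and 3, were added after the data were seen. These segments are runs of at least 3 bins of 2500 locus numbers with at least 20 tested genes, at least 4% of them called at 2-fold in dry libraries labelled tcp14, with at most 1 lower bin between such bins. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library was left out of the main results. Of the genes picked by the naming rule, 1 is not reported here because it is withheld for evaluation.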

Results

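Polyadenylated RNA was sequenced from Arabidopsis thaliana seeds of 3 genotypes, wild type and lines labelled mpk8 and tcp14, taken dry or after 24 h of imbibition, with 3 libraries in each of the 6 groups. MPK8 codes for a mitogen-activated protein kinase and TCP14 for a transcription factor of the TCP family. Per the labels, both lines carry a gene knock out, imbibed seeds were dormant and were kept with water in the dark at 25 °C, and the study concerns the release of dormancy. The labels call the replicates biological without saying whether they come from separate plants or seed lots. Dry libraries held 13201516 to 15753710 counted read pairs in wild type, 17209786 to 18723182 in mpk8 and 13379713 to 21233207 in those labelled tcp14. Imbibed libraries held 12170793 to 16979217, 16746225 to 21087747 and 15605937 to 17100130 pairs in the same order. Across the 18061 genes tested, the first principal component of log2 CPM, counts scaled to a common library size, held 85.2% of the variance and parted dry from imbibed seeds. On it, dry libraries lay between 116.9 and 130, imbibed wild-type libraries between -162.2 and -154.8, imbibed mpk8 libraries between -98.25 and -90.23, and imbibed libraries labelled tcp14 between -122.9 and -106.2.

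The transcripts of both targeted genes were measured in every library. MPK8 (AT1G18150, chromosome 1) stood at 11.4 ± 0.588 CPM (mean ± SD, n = 3) in dry and 11.7 ± 0.849 CPM in imbibed wild-type seeds, against 4.04 ± 0.502 and 4.31 ± 0.397 CPM in the mpk8 line. Its log2 fold change against wild type was -1.49 (SE 0.125, adjusted p = 1.2e-07 by edgeR) in dry and -1.45 (SE 0.104, adjusted p = 6.7e-11) in imbibed seeds, lower in all 3 libraries of each group, a separation that chance gives in 10% of cases with 3 libraries on each side. TCP14 (AT3G47620, chromosome 3) was higher, not lower, in the libraries labelled tcp14: 44.1 ± 0.501 CPM in dry seeds against 6.86 ± 1.40 in wild type, and 34.5 ± 3.14 CPM against 15.73 ± 1.98 after imbibition. These are 6.46-fold (adjusted p = 2.2e-14) and 2.21-fold (adjusted p = 8.9e-10) differences, present in all 3 libraries. The files give 1 count per gene model, so they do not show which part of the TCP14 gene the reads cover. All statements on tcp14 below therefore refer to libraries by their label. TCP14 rose on imbibition 2.296-fold in wild type and 2.203-fold in mpk8 seeds. MPK8 differed from wild type by log2 0.13 (SE 0.107, adjusted p = 0.512) in dry and -0.12 (SE 0.0950, adjusted p = 0.317) in imbibed seeds labelled tcp14, and TCP14 differed by log2 0.06 (SE 0.141, adjusted p = 0.896) in dry mpk8 seeds.

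**Figure D1:**
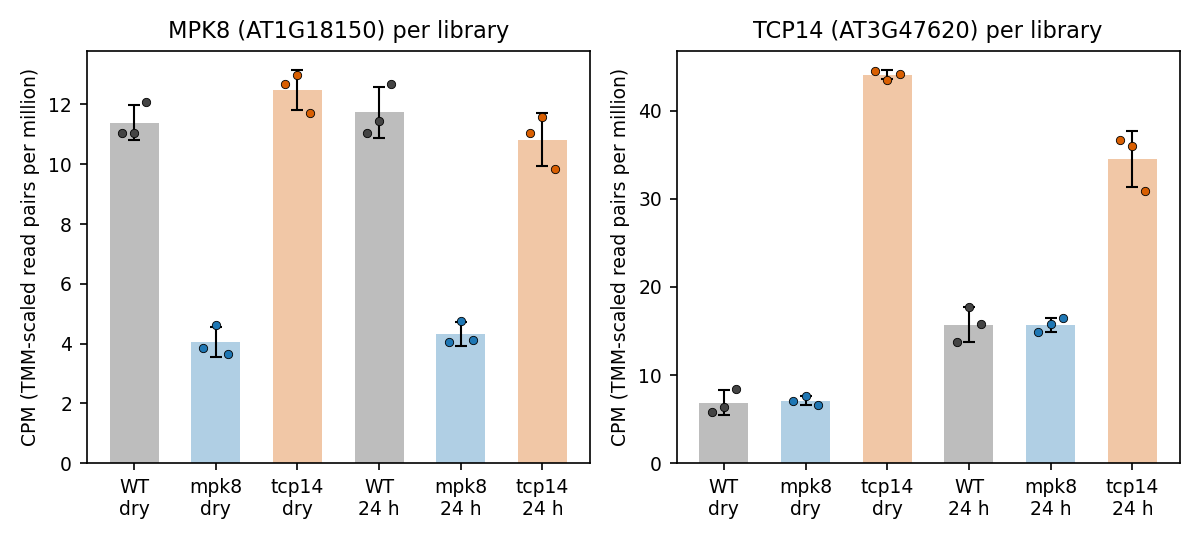
CPM of MPK8 and TCP14 (vertical axes, read pairs scaled to a common library size by TMM) in each library of the 6 groups, where points are libraries, bars are means of 3 and error bars are SD. MPK8 means were 4.04 and 4.31 CPM in mpk8 against 11.4 and 11.7 in wild type, and TCP14 was highest in the libraries labelled tcp14, with means of 44.1 and 34.5 CPM.

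Imbibed against dry wild-type seeds gives the reference course of the first 24 h in water. Seed reserve and protective transcripts fell, and transcripts of translation, cell wall loosening and DNA replication rose. These list calls were lost with an estimated correlation (adjusted p = 0.201 to 0.289). All 14 tested seed storage and oleosin genes fell (median log2 fold change -3.07), among them CRU2, a cruciferin (-3.86, SE 0.111), and OLEO4, an oil body protein (-3.79, SE 0.118). Of 18 late embryogenesis abundant (LEA) genes 17 fell (median -2.70), such as RAB18 (-4.38, SE 0.146), and of 16 heat shock genes 15 fell (median -3.48), such as HSP17.4 (-4.89, SE 0.124) and HSFA9, a seed-specific heat stress factor (-4.24, SE 0.0771). All 16 cytosolic ribosomal protein genes rose (median 2.65), led by RPS6 (3.53, SE 0.0648).

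All 17 genes of DNA replication and the cell cycle also rose in wild type (median 4.02), and PCNA1, the sliding clamp of DNA synthesis, had no read pair in dry seeds and was at least 117.6-fold higher at 24 h. Of 14 cell wall loosening genes 12 rose and 2 fell (median 7.50). XTH31 and XTH4, xyloglucan-modifying enzymes, also had no pair in any dry wild-type library and reached 107.9 ± 7.93 and 22.4 ± 0.567 CPM. Against a floor of 3 pairs over the group, as used for all such bounds here, they were at least 1143-fold and 237.6-fold higher. The same held for CYP81F4, a cytochrome P450 (at least 326.6-fold), TUB5, a beta-tubulin (at least 300.0-fold), CXE13 (at least 224.2-fold), ACO1, an ACC oxidase of ethylene synthesis (at least 217.2-fold), ARAB-1, a GDSL lipase (at least 194.7-fold), and AKN2, an APS kinase (at least 179.4-fold).

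Among genes with a symbol, the steepest losses in wild type were of transcripts present in dry seeds and without a pair at 24 h. VGD1, a pectin methylesterase known from pollen tubes, went from 44.9 ± 1.29 CPM to 0, at least 1068-fold lower, and PGA4, a polygalacturonase, from 41.6 ± 3.40 CPM to 0, at least 988.8-fold lower. VGDH1 (at least 513.5-fold), BGAL11 (402.4-fold), RALFL8 (364.9-fold), RALFL9 (353.9-fold), PYL12, of the abscisic acid (ABA) receptor family (291.4-fold), and ACA3 (256.3-fold) also had no pair after imbibition. DOG1, a central dormancy gene, fell by 5.34 on the log2 scale (SE 0.115). Within the hormone lists, 7 of 9 ABA synthesis genes fell (median -2.32), with NCED6 at -3.33 (SE 0.323), and 10 of 12 genes of gibberellin (GA) perception, DELLA and response rose against 2 that fell (median 3.47), with RGL2, a DELLA repressor of germination, at 5.14 (SE 0.0921), and both list calls were lost with an estimated correlation (adjusted p = 0.201 and 0.206).

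In all, 15547 of the 18061 genes changed on imbibition of wild type, 8300 higher and 7247 lower. Under scaling by library totals, where the median of all genes moves by 1.09 log2 units in wild type, 79.6% of calls were higher instead of 53.4%, and the main values are relative to that shift. Adjusted p values of the list tests were 2.1e-06 for LEA, 2.7e-06 for storage, 2.7e-06 for heat shock, 2.0e-07 for ribosomal, 0.000109 for replication, 0.00115 for cell wall, 0.0122 for ABA synthesis and 0.0149 for GA perception genes. With an estimated correlation the adjusted p was 0.289 for storage, 0.206 for GA perception and 0.201 for the other 6 of these lists. Over all comparisons, 78 of 220 list tests were called with the preset correlation and 3 with an estimated correlation.

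The other lists were not called in wild type, and their counts of genes higher and lower were 4 and 10 of 15 for ABA signalling (median -0.65), 1 and 5 of 7 for dormancy regulators (-0.95), 6 and 10 of 18 for reserve lipid mobilisation (-0.29), 3 and 6 of 13 for jasmonate (-0.38) and 3 and 8 of 13 for MAP kinases (-0.30), all 5 medians being positive under library totals. They were 1 and 1 of 3 for ABA catabolism, 7 and 3 of 10 for GA synthesis, 5 and 4 of 10 for reactive oxygen species, 13 and 2 of 17 for the TCP family, 8 and 2 of 13 for photosynthesis, 1 and 5 of 6 for flavonoids and 1 and 3 of 4 for pathogen defence. Adjusted p values of these 12 lists lay between 0.0662 for ABA signalling and 0.823. The test of reactive oxygen species genes pointed down while their median (0.51) and mean (0.34) were positive. GA catabolism (0 higher, 1 lower), seed coat (2 and 0) and endosperm (1 and 1) had 2 tested members each, too few for a test. Adjusted over the list alone, the counts were the same in all lists except dormancy regulators, where 2 rose instead of 1.

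**Figure D2:**
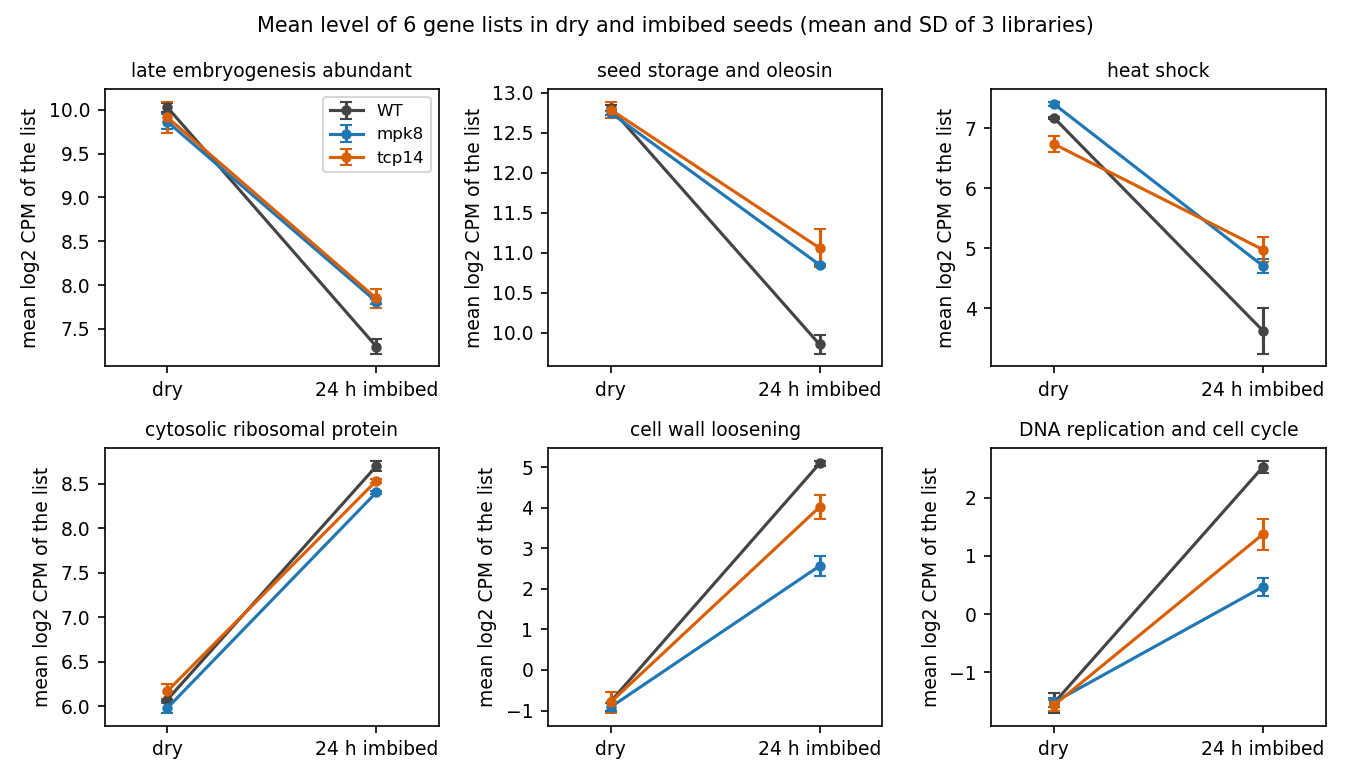
Mean log2 CPM of 6 gene lists (vertical axes) in dry and 24 h imbibed seeds (horizontal axes) of wild type, mpk8 and the libraries labelled tcp14, as mean and SD of 3 libraries. In dry seeds the heat shock list stood at 6.74 ± 0.128 in libraries labelled tcp14, 7.17 ± 0.0145 in wild type and 7.40 ± 0.0386 in mpk8. At 24 h LEA, storage and heat shock genes stood higher in both mutant-labelled groups and ribosomal, cell wall and replication genes lower than in wild type.

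Imbibition of mpk8 and of tcp14-labelled seeds shows whether the same programmes ran in these lines. In mpk8 seeds, 13 of 14 storage genes fell and 1 rose (median -2.14), 17 of 18 LEA genes fell (-2.23, or -2.01 with the member at 0 pairs set at its bound), and all 16 heat shock genes fell (-2.70). All 16 ribosomal protein genes rose (2.45), 12 of 14 cell wall genes rose and 2 fell (5.79, or 5.09 with members at their bound), and 14 of 17 replication genes rose (2.61). JAL34, a lectin, ABCG35, a transporter, and XTH19 had no pair in dry mpk8 seeds and were at least 146.1-fold, 116.1-fold and 113.2-fold higher at 24 h. VGDH1 (at least 357.6-fold lower), PYL12 (305.2-fold) and sks14 (276.1-fold) had no pair after imbibition. LTP4 was at 0 pairs too, from 8.34 ± 7.63 CPM in dry seeds, an SD close to the mean.

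In libraries labelled tcp14, 13 of 14 storage genes fell and 1 rose (median -2.04), all 18 LEA genes fell (-2.18), and 13 of 16 heat shock genes fell and 1 rose (-2.07). All 16 ribosomal protein genes (2.36) and all 17 replication genes (3.19) rose, as did 12 of 14 cell wall genes, with 2 lower (6.78, or 5.57 with members at their bound). Without a pair in dry seeds, scpl44, a serine carboxypeptidase-like gene, was at least 358.7-fold higher, TUB5 108.2-fold, GASA4, a GA-responsive peptide gene, 94.0-fold, LAX2, an auxin influx carrier, 88.5-fold and AKN2 85.9-fold. VGD1 was at least 1121-fold, PGA4 1022-fold and DAF1 246.5-fold lower. TCP14 itself fell by 0.35 (SE 0.0874, adjusted p = 0.000827) on imbibition of these libraries and stood at 0.38 instead under library totals, where the median of all genes moves by 0.73.

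The calls numbered 15017 in mpk8 seeds (8022 higher, 6995 lower) and 15014 in tcp14-labelled seeds (7907 and 7107), and under library totals 77.5% and 75.6% of calls were higher instead of 53.4% and 52.7%. The lists of ABA synthesis, GA perception, LEA, storage, cell wall, ribosomal, heat shock and replication genes were called in both, as in wild type, and lost with an estimated correlation (adjusted p = 0.22 to 0.315). Reserve lipid mobilisation genes were called lower in mpk8 (2 higher, 14 lower of 18, median -0.72, adjusted p = 0.00237, and 0.22 with an estimated correlation) and in tcp14-labelled seeds (4 and 11, median -0.54, adjusted p = 0.0261, and 0.258 with an estimated correlation), with medians of 0.10 and 0.18 under library totals.

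Whether imbibition changed a gene differently in mpk8 than in wild type was tested by the interaction of genotype and imbibition. Storage (14 of 14 with a more positive change, median 1.02), heat shock (13 of 16, with 1 more negative, median 1.203, mean 0.42) and LEA genes (15 of 18, with 2 more negative, median 0.84) fell less in mpk8 than in wild type, list calls lost with an estimated correlation (adjusted p = 0.244 to 0.284). For replication genes the median was -2.16, with 6 of 17 called more negative and 11 not called, and for cell wall genes -2.19, with 3 of 14 called more negative and 11 not called (adjusted p = 0.0881 and 0.0917 with an estimated correlation). WOX2, a homeobox gene of the early embryo, went from 54.3 ± 7.48 to 4.74 ± 0.767 CPM in wild type and from 30.3 ± 1.46 to 8.56 ± 0.569 CPM in mpk8, an interaction of 1.70 (SE 0.146, adjusted p = 1.8e-08). ATBETAFRUCT4, a vacuolar invertase, went from 1.36 ± 0.150 to 9.13 ± 2.11 CPM in wild type and from 0.946 ± 0.231 to 0.226 ± 0.0846 CPM in mpk8 (-4.78, SE 0.636, adjusted p = 3.9e-06).

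The mpk8 interaction was called for 7051 genes, 4336 more positive and 2715 more negative. Under library totals, where its median over all genes moves by -0.27, 26.4% of calls were more positive instead of 61.5%. Its list tests gave an adjusted p of 3.0e-08 for storage, 1.4e-06 for heat shock, 1.5e-05 for LEA, 5.8e-07 for replication and 1.6e-06 for cell wall genes, and an adjusted p of 0.284, 0.244, 0.284, 0.0881 and 0.0917 with an estimated correlation. The counts of these 5 were the same when adjusted over the list alone. Also called were ABA signalling (median 0.43, adjusted p = 0.0301), dormancy (0.74, 0.0150), ribosomal (-0.19, 0.0111), lipid mobilisation (-0.41, 4.7e-05) and photosynthesis genes (-1.12, 0.0396), with an adjusted p of 0.306, 0.0917, 0.543, 0.0917 and 0.568 with an estimated correlation.

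The same test for libraries labelled tcp14, in which TCP14 is higher, gave a like picture of less fall. Storage genes (14 of 14, median 1.27), heat shock genes (15 of 16, median 1.83) and LEA genes (15 of 18, with 1 more negative, median 0.80) fell less than in wild type, while the medians were -0.85 for replication (1 of 17 called, 16 not) and -0.87 for cell wall genes (3 of 14 called, 11 not). With an estimated correlation none of these 5 lists was called (adjusted p = 0.208 to 0.229). ATHSP22.0, a small heat shock protein, went from 37.6 ± 4.77 to 6.88 ± 1.48 CPM in wild type and from 21.4 ± 1.61 to 34.8 ± 3.65 CPM in tcp14-labelled seeds (3.14, SE 0.164, adjusted p = 1.9e-11). CSLC04, an enzyme of xyloglucan synthesis, went from 0.465 ± 0.114 to 15.4 ± 0.968 CPM in wild type and from 2.1 ± 0.622 to 4.71 ± 0.964 CPM there (-3.84, SE 0.372, adjusted p = 1.0e-07).

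This interaction was called for 5991 genes, 3475 more positive and 2516 more negative, and under library totals, with the median over all genes moved by -0.36, 12.01% were more positive instead of 58.0%. The adjusted p was 1.1e-12 for storage, 5.6e-13 for heat shock, 3.3e-07 for LEA, 0.00153 for replication and 0.00282 for cell wall genes, and 0.213, 0.208, 0.229, 0.213 and 0.229 with an estimated correlation. With genes adjusted over the list alone, no replication gene was called and the other counts were the same. Also called were ABA signalling (median 0.35, or -0.018 under library totals, adjusted p = 0.0127), dormancy (0.38, 0.0302), ribosomal (-0.26, 0.00153), lipid mobilisation (-0.28, 0.0302) and photosynthesis genes (-1.47, 0.00213), with an adjusted p of 0.229, 0.213, 0.313, 0.229 and 0.286 with an estimated correlation. Of its 1141 calls of at least 2-fold, 24.1% lay in 2 segments of chromosomes 1 and 3 that hold 16.9% of the tested genes and are described with the dry comparison.

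Imbibed mpk8 against imbibed wild-type seeds asks how the state reached after 24 h in water differs in this line. Storage, LEA and heat shock genes were higher and cell wall and replication genes lower in mpk8, list calls lost with an estimated correlation (adjusted p = 0.103 to 0.279). All 14 storage and oleosin genes were higher (median 0.9998), such as PAP85, a vicilin (1.31, SE 0.120), and CRU3, a cruciferin (1.23, SE 0.144). Of 16 heat shock genes 14 were higher (median 1.42, mean 0.66), with HSP23.6-MITO (1.65, SE 0.111), HSP17.4 (1.63, SE 0.110), HSP101, a disaggregase (1.62, SE 0.128), ATHSP22.0 (1.61, SE 0.120), HSP17.6A (1.60, SE 0.107) and Hsp70b (1.52, SE 0.112) among the largest increases of genes with a symbol and at least 5 CPM. The heat shock gene called lower, HSP18.2, had no pair in mpk8 against 3.10 ± 5.25 CPM in wild type, and this call was lost without replicate 1 of imbibed wild type.

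Cell wall and replication genes stood lower in imbibed mpk8 seeds (adjusted p = 0.154 and 0.103 with an estimated correlation). Of 14 cell wall loosening genes 12 were lower and none higher (median -3.00), with XTH31 at 4.38 ± 1.501 CPM against 107.9 ± 7.93 (log2 -4.64, SE 0.219) and EXPA1, an expansin, at -3.44 (SE 0.154). Of 17 replication and cell cycle genes 15 were lower (median -2.40), among them PCNA1 (-3.42, SE 0.195), and CYCD1;1, a D-type cyclin (-3.03, SE 0.289). Of 13 photosynthesis genes 10 were lower and 1 higher (-1.35), with RBCS3B, a Rubisco small subunit, at -3.23 (SE 0.174). Of 16 ribosomal protein genes 15 were lower by little (-0.26), and of 18 genes of reserve lipid mobilisation 13 were lower and 4 higher (-0.36), with PMDH2, a peroxisomal malate dehydrogenase, at -2.13 (SE 0.146). GA3OX2 (-3.76, SE 0.253) and GA3OX1 (-2.85, SE 0.317), which make active GA, were lower, and so were GASA4 (-3.64, SE 0.182) and GASA6 (-3.07, SE 0.141), which respond to it, but their lists went both ways. Of 10 GA synthesis genes 5 were higher and 3 lower (median 0.16, or -0.17 under library totals, adjusted p = 0.945), and of 12 GA perception and response genes 5 were higher and 4 lower (0.012, or -0.32 under library totals, adjusted p = 0.8601). Both tested seed coat markers were lower (median -0.82), too few for a test.

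The ABA signalling and dormancy lists stood higher in imbibed mpk8 seeds, less so under library totals, and both calls were lost with an estimated correlation (adjusted p = 0.279 and 0.154). Of 15 ABA signalling genes 12 were higher and 3 lower (median 0.43, or 0.099 with 5 higher and 4 lower under library totals), with AHG1, a protein phosphatase, at 0.89 (SE 0.0683) and OST1, a protein kinase, at -1.82 (SE 0.212). Of 7 dormancy regulators 5 were higher and 1 lower (0.52, or 0.18 with 4 and 1 under library totals), with DOG1 at 0.996 (SE 0.165) and SOM at 0.92 (SE 0.0697). CYP707A3, an ABA 8'-hydroxylase, was lower (-1.87, SE 0.205), but its list of 3 tested ABA catabolism genes was not called. The list had a median of -0.55, while its summed level was 49.7 CPM in mpk8 against 41.1 in wild type. Of 18 LEA genes 15 were higher and 2 lower (0.91, mean 0.40), with M10 at 1.18 (SE 0.0996) and ERD10 at -3.13 (SE 0.396). Outside the lists, MLP31 (1.68, SE 0.0987) and BAG6, a co-chaperone (1.56, SE 0.133), were higher. Among genes with a symbol, at least 5 CPM in the higher group and no overlap of libraries, the largest decreases were of ATBETAFRUCT4 (-5.30, SE 0.341), scpl44 (-5.24, SE 0.238), CYP81F4 (-5.22, SE 0.281), CER1, a wax synthesis gene (-4.91, SE 0.310), AGP18, an arabinogalactan protein (-4.80, SE 0.334), SCPL9 (-4.71, SE 0.304) and SCPL34 (-4.67, SE 0.337).

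Across all genes, 6096 were higher and 5567 lower in imbibed mpk8 seeds, and of the 2871 calls of at least 2-fold 403 were higher and 2468 lower. Under library totals, which move the median of all genes by -0.33, 19.8% of the calls were higher instead of 52.3% (48.6% with DESeq2 size factors), while the medians of the 10 called lists kept their sign. List tests gave an adjusted p of 5.4e-07 for storage, 9.3e-07 for heat shock, 1.3e-06 for cell wall, 9.3e-07 for replication, 3.2e-05 for LEA, 0.000241 for ribosomal, 0.00818 for lipid mobilisation, 0.0139 for photosynthesis, 0.0139 for ABA signalling and 0.0229 for dormancy genes. With an estimated correlation the adjusted p was 0.279, 0.26, 0.154, 0.103, 0.279, 0.318, 0.26, 0.445, 0.279 and 0.154 in that order. The 10 counts were the same when adjusted over the list alone. For ABA synthesis 6 of 9 were higher and 1 lower (median 0.45), and the test was not called (adjusted p = 0.0782).

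Imbibed tcp14-labelled against imbibed wild-type seeds asks the same of the other line, in libraries where TCP14 is higher. The same lists were called in the same directions, and all 10 calls were lost with an estimated correlation (adjusted p = 0.184 to 0.477). All 14 storage genes were higher (median 1.23), with CRU3 at 1.71 (SE 0.146) and SESA4, a 2S albumin, at 1.69 (SE 0.0923). These libraries spread more than the others: the mean log2 CPM of the storage list was 11.06 ± 0.238, against 10.85 ± 0.0142 in mpk8 and 9.855 ± 0.117 in wild type (mean ± SD, n = 3). Replicate 3 lay nearest to the dry libraries on the first principal component, at -106.2. Of 16 heat shock genes 14 were higher and none lower (1.48), led by ATHSP22.0 (2.33, SE 0.117), HSP23.6-MITO (1.83, SE 0.112) and HSP17.6A (1.82, SE 0.108). Of 18 LEA genes 15 were higher and 2 lower (0.77), with M10 at 1.43 (SE 0.1001) and ERD14 at -1.28 (SE 0.231). Of 15 ABA signalling genes 10 were higher and 3 lower (0.35, or 0.014 with 4 higher and 4 lower under library totals), and of 7 dormancy regulators 5 were higher (0.33, or -0.0044 with 3 higher and 1 lower under library totals), with DOG1 at 0.91 (SE 0.171).

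Cell wall and replication genes were lower in the imbibed libraries labelled tcp14 as well (adjusted p = 0.211 and 0.184 with an estimated correlation). Of 14 cell wall genes 12 were lower (median -1.18), with XTH4 at -2.101 (SE 0.173) and XTH31 at -1.48 (SE 0.172). Of 17 replication genes 15 were lower and 1 higher (-1.32), with CYCD3;1 at -2.097 (SE 0.289) and CDT1A, a replication licensing factor, at -1.69 (SE 0.211). Of 13 photosynthesis genes 11 were lower (-1.80), with LHCB3, a light-harvesting protein, at -2.92 (SE 0.483). Of 16 ribosomal protein genes 10 were lower (-0.17), and of 18 lipid mobilisation genes 11 were lower and 3 higher (-0.25). GA3OX2 (-2.22, SE 0.217), GA3OX1 (-1.82, SE 0.287), GASA4 (-1.97, SE 0.158) and CYP707A3 (-1.44, SE 0.199) were lower, while of 10 GA synthesis genes 4 were higher and 2 lower (median 0.20, or -0.13 under library totals, adjusted p = 0.852) and of 12 GA perception and response genes 3 were higher and 4 lower (0.012, or -0.33 under library totals, adjusted p = 0.986). The ABA catabolism list of CYP707A3 was not called, with a mean log2 CPM of 2.31 against 2.90 in wild type and a summed level of 41.6 against 41.1 CPM. Both tested seed coat markers were lower here too (median -0.83).

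Among genes with a symbol outside the lists, the largest differences in imbibed tcp14-labelled seeds lay mostly on chromosomes 1 and 3. TIF3C2, a translation initiation factor subunit gene (AT3G22860), stood at 8.36 ± 0.842 CPM against 0.0423 ± 0.0382 in wild type. ADT4, an arogenate dehydratase (AT3G44720, log2 5.22, SE 0.1997), ANNAT1, annexin 1 (AT1G35720, 3.18, SE 0.107), SADHU10-1 (AT3G58865, 3.10, SE 0.206), UGT85A3 (AT1G22380, 2.59, SE 0.161) and CYP71B18 (AT3G26165, 1.99, SE 0.0563) were higher. PLC8 (AT3G47290) had no pair in these libraries against 10.4 ± 0.582 CPM in wild type, at least 215.6-fold lower, HSD2 (AT3G47350) stood at 0.0293 ± 0.0508 against 11.7 ± 0.532 CPM, LpxC2 (AT1G24880) at 0.0147 ± 0.0254 against 6.50 ± 1.12 CPM, and HSD3 (AT3G47360) was at -6.79 (SE 0.216).

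Across all genes 4925 were higher and 5052 lower in imbibed tcp14-labelled seeds, 391 and 1755 of them by at least 2-fold, and 12.6% of calls were higher under library totals instead of 49.4%, with a shift of the median by -0.33. Of the 2-fold calls, 23.5% lay in the 2 segments. List tests gave an adjusted p of 3.8e-11 for storage, 4.6e-10 for heat shock, 1.4e-06 for LEA, 0.000756 for cell wall, 0.000167 for replication, 0.000756 for photosynthesis, 0.0091 for ribosomal, 0.0122 for lipid mobilisation, 0.0298 for ABA signalling and 0.0298 for dormancy genes. With an estimated correlation the adjusted p was 0.211, 0.184, 0.211, 0.211, 0.184, 0.285, 0.477, 0.211, 0.285 and 0.184. Adjusted over the list alone the counts were 11 higher and 4 lower for ABA signalling and 5 and 1 for dormancy regulators, and the same for the other 8.

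**Figure D3:**
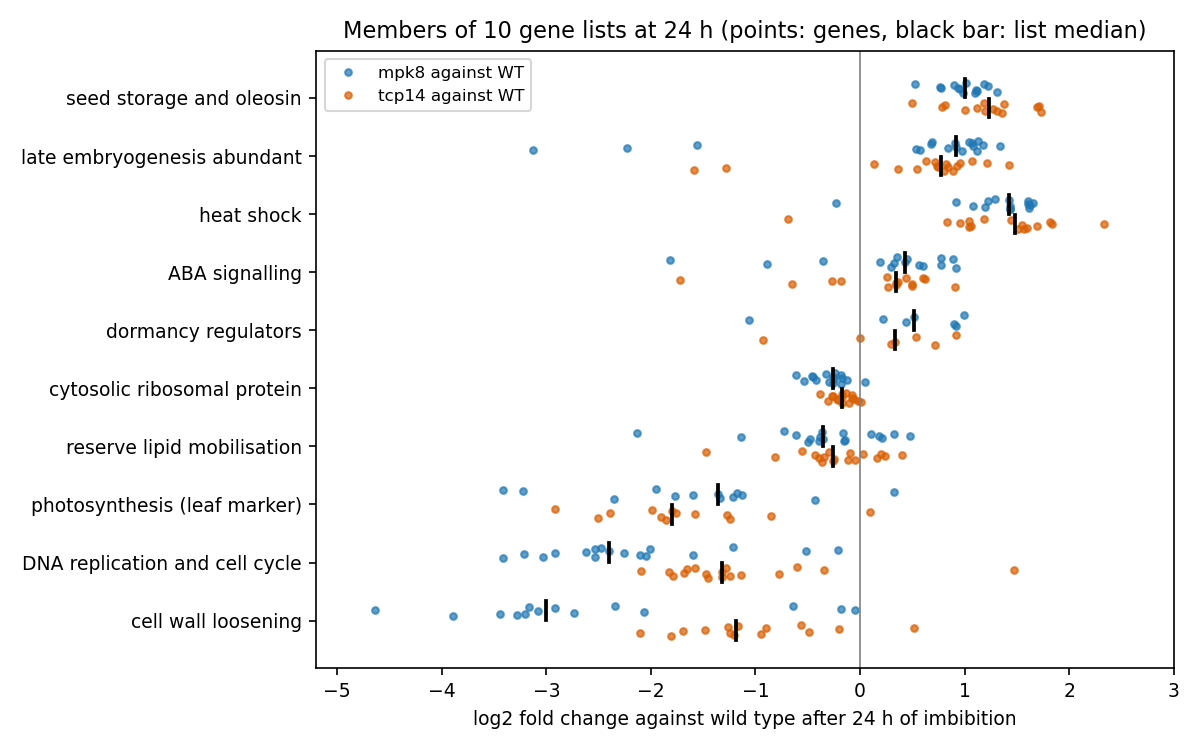
Log2 fold change against wild type at 24 h (horizontal axis) of the members of 10 gene lists in mpk8 and in libraries labelled tcp14, where points are genes and black bars list medians; HSP18.2 in mpk8, with no read pair, is not drawn. Storage, LEA and heat shock genes lie to the right and replication and cell wall genes to the left in both, and the median of dormancy regulators in the libraries labelled tcp14 turns from 0.33 to -0.0044 under library totals.

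The overlap of both lines at 24 h asks how far they share a response. Of the called genes, 8932 were shared in the same direction, 4478 higher and 4454 lower, which is 89.5% of the smaller set, and 122 were called in opposite directions. Under library totals 1167 shared genes were higher and 8223 lower, and of those past 2-fold in both lines 201 were higher and 1534 lower. Among shared genes with a symbol and at least 5 CPM, the 10 with the largest changes were all lower in both. UMAMIT44, an amino acid transporter family gene, was at -3.73 (SE 0.239) in mpk8 and -5.01 (SE 0.288) in tcp14-labelled seeds, and AGAL2, an alpha-galactosidase, at -4.57 (SE 0.220) and -2.63 (SE 0.181). MES10 (-3.79 and -3.36), RPT2, of phototropic signalling (-4.55 and -2.93), APE2, the chloroplast triose phosphate translocator (-3.37 and -2.51), MLP28 (-3.73 and -2.44), OMT1, an O-methyltransferase (-2.77 and -2.37), PSBQA, of photosystem II (-3.62 and -2.34), UGD1, a UDP-glucose dehydrogenase (-2.95 and -2.32), and AGP18 (-4.80 and -2.32) followed.

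If calls fell independently, 3219 shared genes would arise, and the log2 fold changes of both lines had r = 0.708 across genes, which are not independent replicates. Both comparisons share the wild-type libraries: in 20 simulations without any genotype effect the shared libraries alone gave a mean r of 0.478, a mean of 0.1 shared calls and a covariance of 0.0253, against 0.569 observed. A control group of 3 libraries cannot be split into separate sets of 2, so part of the excess may rest on the shared controls. Of the shared genes 2480 differed between the lines when these were compared directly, and 1735 passed 2-fold in both.

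**Figure D4:**
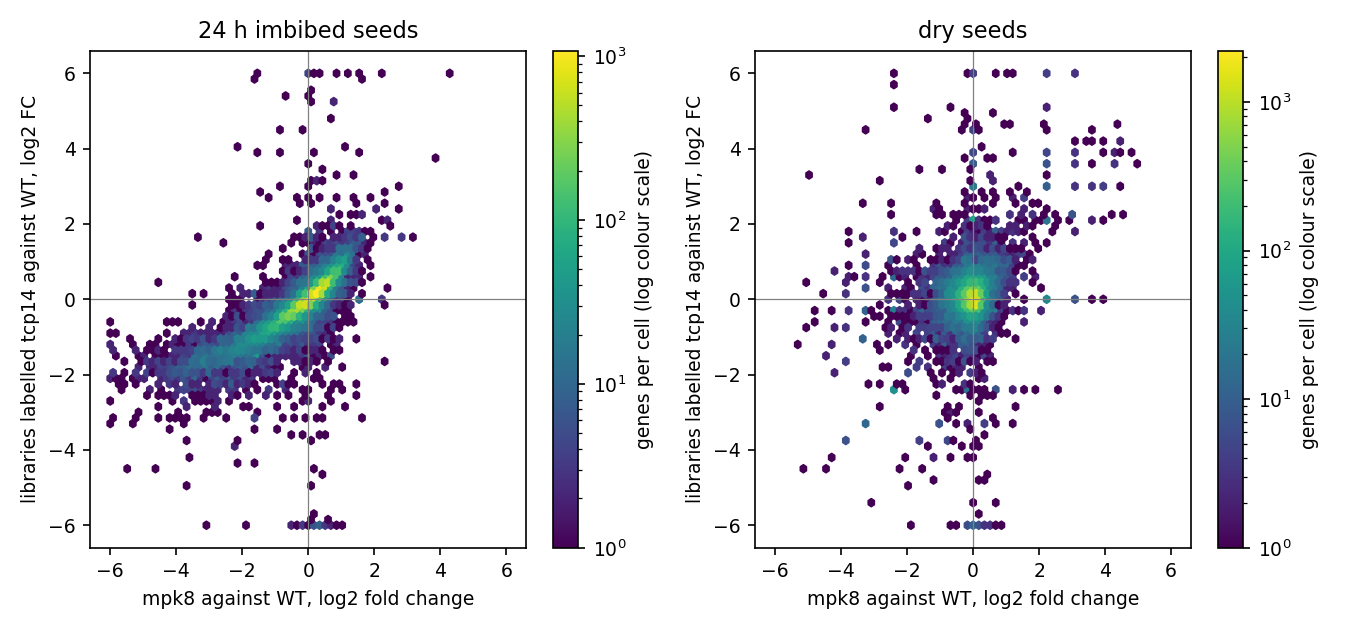
Log2 fold change against wild type of each tested gene in mpk8 (horizontal axes) and in libraries labelled tcp14 (vertical axes), in imbibed and in dry seeds, with colour for the number of genes per cell and values beyond 6 drawn at 6. The cloud follows the diagonal at 24 h (r = 0.708 across genes) and spreads along the vertical axis in dry seeds (r = 0.296).

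Dry mpk8 against dry wild-type seeds asks what differed before any water was taken up. Fewer genes were called than in any other comparison. MLP31, of the major latex protein family, was higher at 1669 ± 21.1 against 1084 ± 55.5 CPM (log2 0.62, SE 0.0962, adjusted p = 0.00102), as were FIP1, a FRIGIDA interactor (0.68, SE 0.0712, adjusted p = 5.6e-06), CYP81D11 (0.64, SE 0.107) and MYB3R-4, a cell cycle transcription factor (0.59, SE 0.109). RABG3E, a small GTPase, was lower at 10.6 ± 0.929 against 49.1 ± 2.69 CPM (-2.21, SE 0.0740, adjusted p = 1.3e-15), as were MRD1 (-2.48, SE 0.167), MPK8 and VGDH2, of a family known from pollen tubes (-1.12, SE 0.175). Of the storage genes 1 of 14 was called, of the LEA genes 2 of 18, both lower, and no member of the heat shock, cell wall, dormancy, ribosomal or replication lists.

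The calls numbered 473 (277 higher, 196 lower), 54 of them of at least 2-fold (4 higher, 50 lower), 838 with all genes kept and 1045 in a fit of the 2 groups alone, and 19.9% of calls were higher under library totals instead of 58.6%. The count fell to between 117 and 232 when any 1 of the 6 libraries was left out, lowest without replicate 1 of dry wild type, and 8 of the 16 genes with the largest changes lost their call in at least 1 of these fits. The called lists were lipid mobilisation higher (median 0.13, adjusted p = 1.6e-05), ribosomal lower (-0.09, adjusted p = 0.0078) and heat shock higher (0.16, adjusted p = 0.0289), with an adjusted p of 0.113, 0.723 and 0.723 with an estimated correlation. Adjusted over the list alone, 11 of 18 lipid mobilisation genes were higher, 2 of 16 ribosomal genes lower and 4 of 16 heat shock genes higher, against 1, 0 and 0 over all genes.

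Dry tcp14-labelled against dry wild-type seeds asks the same of the other line. The largest differences of genes with a symbol were of single genes that were near absent in 1 genotype. CYP71A22 (AT3G48310) had no pair in dry wild type against 5.18 ± 0.519 CPM, at least 54.9-fold higher, TIF3C2 stood at 15.1 ± 1.76 against 0.0630 ± 0.0554 CPM, CYP94B3 (AT3G48520) at 6.02 ± 0.625 against 0.211 ± 0.213 CPM, and 5PTASE11 (AT1G47510) at 5.97 ± 0.752 against 0.393 ± 0.257 CPM. ANNAT1 (2.15, SE 0.104), CYP71B18 (2.47, SE 0.0568) and NGA2 (2.14, SE 0.191) were also higher. HSD3 and HSD2, steroleosin family genes next to each other on chromosome 3, had no pair in the tcp14-labelled libraries and were at least 81.7-fold and 69.6-fold lower. ABCC9 (AT3G60160) stood at 0.210 ± 0.0716 against 54.4 ± 3.08 CPM and ABCC15 (AT3G60970) at 0.334 ± 0.167 against 40.3 ± 2.296 CPM, and CYP81D11 (-3.08, SE 0.170), HCEF1 (-2.63, SE 0.132), RPP1, a resistance gene (-2.41, SE 0.0764), and CYCD3;3 (-2.21, SE 0.232) were lower.

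All of these named genes lie on chromosomes 1 and 3. Of the 377 calls of at least 2-fold, 280 (74.3%) lay in 2 segments, AT1G20010 to AT1G47490 on chromosome 1 and AT3G20000 to AT3G62470 on chromosome 3, which hold 16.9% of the tested genes (odds ratio 15.5, Fisher's exact p = 7.3e-137; the segments were set on these same calls). TCP14 lies in the second. The same genes in mpk8 against wild type showed no such share, with 14 of 54 2-fold calls there (25.9%, Fisher's exact p = 0.0985). Heat shock genes were lower in dry tcp14-labelled seeds (7 of 16, median -0.24, adjusted p = 0.000418, and 0.9998 with an estimated correlation), among them HSP17.6II (-1.38, SE 0.158) and ATHSP22.0 (-0.81, SE 0.114), and no other list was called. The count was the same when adjusted over the list alone.

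The calls numbered 2058, 1106 higher and 952 lower, and 1005 outside the segments. Which direction held more genes depended on the processing: 953 were higher and 1152 lower with DESeq2 size factors, 805 and 1106 with the DESeq2 Wald test, 1180 and 1370 in a fit of the 2 groups alone, and 1207 and 717 under library totals. Without replicate 2 of dry wild type the count was 1347. Dry calls of both lines had 39 genes in common in the same direction, 30 higher and 9 lower (11 and 13 under library totals), and 99 in opposite directions. More genes were thus called in opposite directions than in the same one, where independent calls would give 27.3 in the same direction. The 39 were 92 with all genes kept and 87 in fits of the compared groups alone, and fell to between 11 and 23 when a wild-type or mpk8 dry library was left out, lowest without replicate 1 of dry wild type. The log2 fold changes had r = 0.296 across genes against a mean of 0.556 in the simulations with shared wild-type libraries alone, while their covariance was 0.133 against a mean of 0.112.

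**Figure D5:**
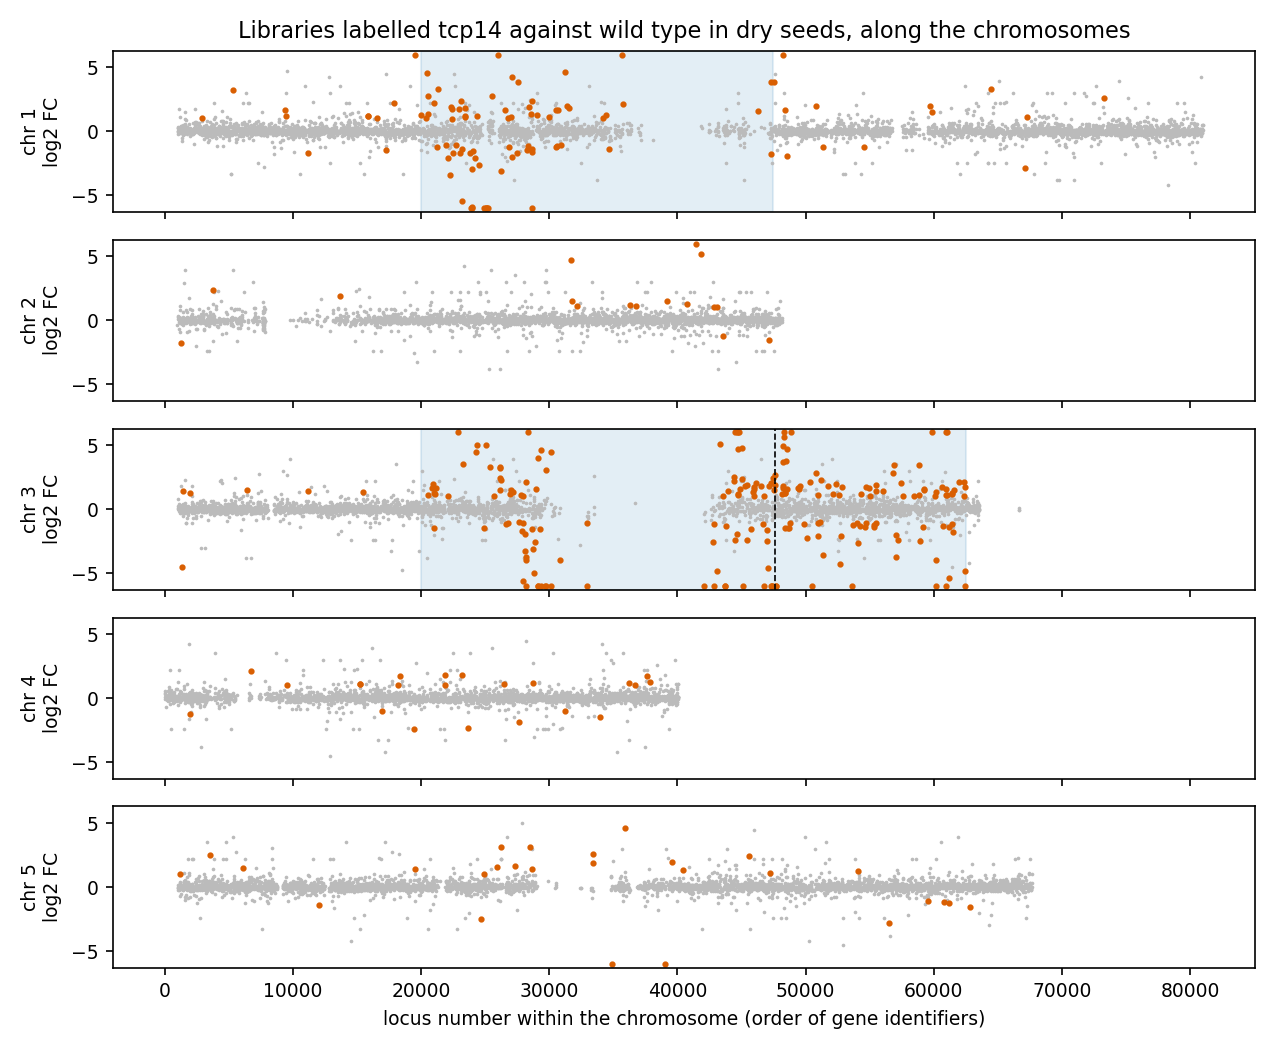
Log2 fold change (vertical axes, limited to 6 either way) of tested genes in dry libraries labelled tcp14 against wild type, by locus number along the 5 chromosomes (horizontal axis), with calls of at least 2-fold in orange, other genes in grey, the 2 segments shaded and TCP14 marked by the dashed line. Of the 377 orange points, 280 lie in the shaded segments.

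A direct comparison of mpk8 with tcp14-labelled seeds shows where the lines differ from each other. In dry seeds, heat shock genes were higher in mpk8 (10 of 16, median 0.48), with HSP21 at 2.01 (SE 0.388) and HSP17.6II at 1.77 (SE 0.153), a list call lost with an estimated correlation (adjusted p = 0.376). Of 16 ribosomal protein genes 8 were lower in mpk8 (-0.18), and of 18 lipid mobilisation genes 7 were higher (0.09, or -0.0044 under library totals), with an adjusted p of 0.771 and 0.25 with an estimated correlation. The single genes with a symbol and the largest differences were those named for tcp14-labelled dry seeds: HSD3 and HSD2 without a pair in the latter (at least 74.0-fold and 71.0-fold higher in mpk8), ABCC9 and ABCC15, and in the other direction TIF3C2, CYP71A22, CYP94B3 and 5PTASE11. The calls numbered 4522 (2294 higher in mpk8, 2228 lower), 26.0% of them higher under library totals instead of 50.7%, and 49.7% of the 723 2-fold calls lay in the segments. The adjusted p was 2.0e-05 for heat shock, 0.00306 for ribosomal and 0.00401 for lipid mobilisation genes, and 0.376, 0.771 and 0.25 with an estimated correlation. Adjusted over the list alone 12 heat shock genes were higher, 11 ribosomal genes lower and 7 lipid mobilisation genes higher.

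In imbibed seeds, cell wall and replication genes were lower in mpk8 than in tcp14-labelled seeds. Of 14 cell wall genes 11 were lower (median -1.53), with XTH31 at -3.16 (SE 0.223) and EXPA1 at -2.49 (SE 0.153), and of 17 replication genes 13 were lower (-0.96), with PCNA1 at -1.96 (SE 0.216). Of 13 jasmonate genes 6 were lower and 1 higher (-0.41), with JAZ8 at -1.47 (SE 0.244), and GASA6 (-2.28, SE 0.143) and GASA4 (-1.67, SE 0.2001) were lower. Of 14 storage genes 6 were lower in mpk8 (-0.18) and of 16 ribosomal protein genes 6 (-0.11), with an adjusted p of 0.83 and 0.569 with an estimated correlation. PLC8, HR4, LpxC2 and HSD2 were near absent in tcp14-labelled seeds, PLC8 at least 149.8-fold higher in mpk8, whereas ADT4 (-5.2, SE 0.1995), TIF3C2, scpl44 (-3.93, SE 0.246) and CYP81F4 (-3.69, SE 0.303) were lower in mpk8.

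The imbibed lines differed in 3796 genes, 1707 higher and 2089 lower in mpk8, and 33.2% of the 984 2-fold calls lay in the segments. A fit of these 6 libraries alone called 2351 genes. The adjusted p was 1.7e-08 for cell wall, 5.1e-07 for replication and 0.00782 for jasmonate genes, each with an adjusted p of 0.0443 with an estimated correlation, and these are the 3 lists called both ways. For storage it was 0.0225 and for ribosomal genes 0.00221, and 0.83 and 0.569 with an estimated correlation. Adjusted over the list alone 7 ribosomal genes were lower and 2 jasmonate genes higher, and the other counts were the same.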

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

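The segment tests, the scaling and seed lot tests and the label tests in this part were chosen only after the result was seen, while the splits and the mixture test were set before.

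Imbibition changed 7051 genes differently in mpk8 than in wild type by a test of the difference itself. Among named genes the differences were AGP6 2.52, HAT2 2.50, scpl39 1.82, CYP71B3 1.797, PIF7 1.76, AGP11 1.73, PMT6 1.73 and WOX2 1.70 upwards and PDLP3 -6.53, GUS3 -5.90, NSH3 -5.88, HEXO3 -5.48, ATBETAFRUCT4 -4.78, CYP81F2 -4.77, MSRB9 -4.73 and UGT72E2 -4.46 downwards. Of these 16 genes, 2 have a group at 0 pairs and 9 a group with 3 pairs or fewer, so their fitted values depend on the prior count and give no bound. List medians differed for heat shock (1.203), storage (1.02), LEA (0.84), dormancy (0.74), ABA signalling (0.43), ribosomal (-0.19), lipid mobilisation (-0.41), photosynthesis (-1.12), replication (-2.16) and cell wall genes (-2.19), and all 10 calls were lost with an estimated correlation (adjusted p = 0.0881 to 0.568).

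In libraries labelled tcp14 the difference was called for 5991 genes, and TCP14 itself was at -1.55. Named genes were 5PTASE11 4.07, ATHSP22.0 3.14, HSP21 2.79, HSP23.6-MITO 2.61, ATL15 2.47, CYP71B26 2.40 and HSP17.4 2.24 upwards and SUC1 -4.6, HEXO3 -4.26, CSLC04 -3.84, PMEPCRA -3.745, UMAMIT25 -3.71, RPT2 -3.58, OCT1 -3.575 and EXT3 -3.53 downwards. Of the 16 genes picked by the naming rule, 1 has a group at 0 pairs and 6 a group with 3 pairs or fewer. List medians differed for heat shock (1.83), storage (1.27), LEA (0.80), dormancy (0.38), ABA signalling (0.35, or -0.018 under library totals), ribosomal (-0.26), lipid mobilisation (-0.28), replication (-0.85), cell wall (-0.87) and photosynthesis genes (-1.47), and all 10 calls were lost with an estimated correlation (adjusted p = 0.208 to 0.313).

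Other splits of the same libraries were refitted with the compared groups alone. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split was the 1 with the most genes in each comparison. Real and highest other counts were 15160 and 0 for imbibition in wild type, 14370 and 0 in mpk8, 13949 and 0 in tcp14-labelled seeds, 1045 and 3 for mpk8 and 2550 and 0 for tcp14-labelled against wild type in dry seeds, 11699 and 0 and 9127 and 0 at 24 h, and 5033 and 0 dry and 2351 and 0 at 24 h between the lines. For the mpk8 interaction 5 of 50 splits gave as many genes (real 7212, highest other 7631), so chance is not excluded. The 4 others all keep the genotypes apart at 24 h, and the highest split that does not gave 1 gene, which points to a structure of the samples. For the tcp14-labelled interaction (5583, highest other 4075) and the 24 h overlap (8732, highest other 8042, with the wild-type libraries as the reference) only the real split of 50 reached the real value. This is the smallest share that 50 splits can give. The highest other split keeps the genotypes apart at 24 h in the first and the wild-type libraries together in the second. These splits therefore do not exclude chance. For the dry overlap 2 of 50 splits reached the real value (87, highest other 1927, with the 3 dry tcp14-labelled libraries as the reference), a share under 0.05. The higher split, many times the real count, points to a structure of the samples: the dry tcp14-labelled libraries differ from the other 6. No split with a reference of mixed genotypes gave a shared gene, so the share reflects how few splits keep a genotype together as the reference. With the 3 dry mpk8 libraries as the reference the count was 76, near the real 87. The dry splits do not exclude chance either.

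Large dry differences of the tcp14-labelled libraries cluster on chromosomes 1 and 3. A local effect of a change at TCP14, on chromosome 3, would not account for the calls on chromosome 1. In that segment 2-fold calls between the lines at 24 h had an odds ratio of 2.54 (10.4% against 4.38% of genes, Fisher's exact p = 6.0e-15). Of these calls 33.2% lie in the segments, which hold 16.9% of genes, and 657 of the 984 lie outside. The segments were set on dry calls of the same line, so any lasting difference recurs in them at 24 h. These shares therefore do not decide on regulation spread over the genome. DNA of another accession in the segments may explain the cluster, a hypothesis only. Dry and 24 h changes of the 280 segment genes had r = 0.903 across genes, against 0.615 for 97 genes outside. Any lasting difference of the line would repeat in this way, so r does not tell the causes apart. Sequence was not analysed here.

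On the first principal component, imbibed libraries of both lines lie between dry and imbibed wild-type libraries. On the second, with 4.75% of the variance, they do not. There dry libraries (-11.87 to 2.68) lie between imbibed wild-type (-54.87 to -43.63) and imbibed mpk8 (37.84 to 52.4) or tcp14-labelled libraries (6.47 to 29.85). Across genes, the 24 h difference of mpk8 had r = -0.477 with imbibition of tcp14-labelled seeds. That of tcp14-labelled seeds had r = -0.297 with imbibition of mpk8. Scaling is argued against, since 1 factor per library moves every gene alike and cannot part lists, while storage genes stood at least 0.951 above the median of all genes and replication genes at -1.31 or lower from it. A mixture of seeds still in the dry state with seeds like wild type is argued against by the share of dry-type RNA it needs, 37.0% by ribosomal and 90.9% by cell wall genes in mpk8 and 32.5% and 68.3% by ribosomal and replication genes in tcp14-labelled seeds, gaps of 53.9 and 35.8 points. Seed lots of differing age or dormancy cannot be told apart from genotype, because each genotype may be 1 lot, and the 39 dry calls shared by both lines do not decide it. The mixture test covered only seeds at the transcript levels of dry seeds. A slower or blocked course in both lines, in all seeds or in a share of them, stays open as a biological hypothesis.

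TCP14 is higher in the libraries labelled tcp14. An exchange of mpk8 and tcp14 labels is argued against by MPK8. Against wild type it was lower in libraries labelled mpk8 (log2 -1.49 dry, -1.45 imbibed) and not in those labelled tcp14 (0.13 dry, -0.12 imbibed). After an exchange, the drop of MPK8 would lie in the tcp14 line. This argument assumes that a knock out lowers the transcript of its own gene, which TCP14 does not show, so it is not decisive. An exchange of wild-type and tcp14 labels is argued against by TCP14 at 0.0608 in dry mpk8 against wild type, 2 groups that would then differ. Transcript from an insertion or from another allele over part of the gene cannot be told apart from more full-length transcript, since the value of 2.69 rests on 1 count per gene model. The data hold no measure of TCP14 protein or function.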

How the results depend on the processing

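Single reads and genes outside the segments of chromosomes 1 and 3 were chosen after the results were seen. Of 876 values of named genes, 871 kept direction and call with DESeq2 size factors, 870 with all genes, 871 with the replicate block, 860 with single reads and 801 with library totals, 841 of 866 with DESeq2's test, 837 of 854 with the compared groups alone, 332 of 337 outside the segments, 5897 of 6270 with 1 library left out, and 613 of 876 with a 2-fold minimum. Replicate numbers were not taken to pair libraries, since only 15 of 45 same-number pairs had r over 0.1 (-0.245 to 0.38), though the own number was best in 22, more than the 15 chance gives, and the replicate block moved dry mpk8 calls from 473 to 488. Of 220 list tests 145 kept their side with an estimated correlation and 220 with the replicate block.

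Library totals reversed CYP707A2 (0.82 imbibed wild type, 0.32 imbibed tcp14, -0.17 tcp14 at 24 h), CYP707A1 (0.27 imbibed mpk8, 0.26 imbibed tcp14), MUM4 (0.32, 0.33), LCR67 (0.028, 0.016), MPK8 (0.53) and TCP14 (0.38) on imbibition of tcp14, TCP14 in mpk8 at 24 h (-0.33), HUB1 in tcp14 at 24 h (-0.0044) and MPK6 in the tcp14 interaction (-0.16), by the shift of the median of all genes.

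A 2-fold minimum left 10153, 8913 and 8700 genes for imbibition of wild type, mpk8 and tcp14, 54 and 377 dry, 2871 and 2146 at 24 h, 723 and 984 between lines, 1518 and 1141 interactions and 1735 and 5 shared. Dry mpk8 calls were 838 with all genes and 1045 with the 2 groups alone, those between lines at 24 h 2351, dry tcp14 calls outside the segments 1005, and dry shared calls 24 with totals, 92 with all genes and 87 with the groups alone; the cause was not tested.

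With 1 library left out, counts ran from 117 (WT dry replicate 1) to 232 for dry mpk8, 1347 to 1604 for dry tcp14, 11 to 36 for dry shared, 2554 to 4441 and 3550 to 3852 between lines at 24 h and dry, 10829 to 11444 and 8834 to 9837 for mpk8 and tcp14 at 24 h, 15336 to 15499, 14542 to 14769 and 14625 to 15037 for imbibition, 6356 to 7021 and 5266 to 6433 for interactions and 7938 to 8910 for the 24 h overlap. The cause was not tested. Depth limits genes near zero.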

Other observations

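The gene families below and the genes that differed from wild type in both lines and both states were chosen after the data were seen. The test on pollen transcripts was written before its values were seen.

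Beyond the fixed lists, 14 gene families were tested at 24 h. With the preset correlation, aquaporin, peroxidase and serine carboxypeptidase-like genes were called lower in both lines, and histone and SAUR-like genes in mpk8 only. Of these, only peroxidase genes in tcp14-labelled seeds were also called with an estimated correlation (adjusted p = 0.0413 by camera). Cytochrome P450, glutathione S-transferase, pentatricopeptide repeat, proteasome, UDP-glycosyltransferase and WRKY genes were called in neither line. GDSL lipase genes, which code for secreted esterases, were lower in both lines: 35 of 47 lower and 3 higher in mpk8 (median -1.29, adjusted p = 6.1e-08, and 0.0377 with an estimated correlation) and 33 and 2 in tcp14-labelled seeds (-1.11, adjusted p = 2.6e-06, and 0.0413 with an estimated correlation). Arabinogalactan protein genes were lower too, 25 of 35 with 4 higher (-1.30, adjusted p = 0.000106, and 0.0377 with an estimated correlation) and 23 with 2 higher (-1.21, adjusted p = 0.000377, and 0.0413 with an estimated correlation). Tubulin genes, 16 of 18 of which rose on imbibition of wild type, were lower for 14 of 18 and higher for 2 in each line (adjusted p = 0.000106 in mpk8 and 0.000377 in tcp14-labelled seeds, and 0.114 and 0.144 with an estimated correlation).

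AT3G01345 and AT5G35935 were the 2 genes that differed from wild type at least 2-fold in the same direction in both lines and both states. Both lines were set against the same wild-type seeds, so a change in the lines cannot be told apart from a difference of those seeds. AT3G01345 was lower, at 46.2 CPM in dry and 94.2 in imbibed wild type and with log2 fold changes of -5.11 and -5.54 in mpk8 and -4.52 and -4.49 in tcp14-labelled seeds. AT5G35935 was higher, at 0.261 and 1.41 CPM in wild type, 5.36 and 21.0 in mpk8 and 6.28 and 18.0 in tcp14-labelled seeds.

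Dry wild-type seeds held VGD1 and PGA4, known from pollen, at 44.9 and 41.6 CPM. From a separate list of 26 pollen genes without these, written before the test, 13 reached 1 CPM in dry wild type. Of these, 12 had a lower mean in dry mpk8, as pollen RNA carried on seeds in differing amounts would give, while 11 had a higher mean in dry tcp14-labelled seeds. Picking genes on the dry wild-type values favours a lower mean in the other lines, so the count of 12 does not decide on pollen. Listed genes below 1 CPM went both ways, such as LLG2 (0.521 CPM in dry mpk8 against 0.474 in wild type) and LLG3 (0.105 against 0.395). Few passed singly: of 17 tested genes 2 were called lower in dry mpk8 and 1 higher in dry tcp14-labelled seeds. The camera test of the list gave p = 0.00017 in dry mpk8 and 0.0286 in dry tcp14-labelled seeds, and 0.0447 and 0.217 with an estimated correlation. The most abundant in dry wild type were SKS13 at 49.97 and MYB101 at 16.2 CPM, and MYB101 stood at 17.9 CPM in imbibed wild type too, so seed tissue can express it. Sums over the 13 genes that reached 1 CPM, a set picked on the dry wild-type values, were 77.5 ± 3.16 CPM in mpk8, 104.6 ± 5.46 in wild type and 126.8 ± 24.0 in tcp14-labelled dry seeds (mean ± SD, n = 3). At 24 h they were 20.6, 21.7 and 16.8 CPM in the same order. Pollen carried on dry seeds may therefore be a source of part of the dry differences, a hypothesis only, since the seed itself could also make these transcripts.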
